A study of Homo sapiens with 9 samples.

How the data were processed

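HepG2 cells with a control shRNA or 1 of 2 SETD2 shRNAs were profiled for m6A, with 3 labelled replicates per shRNA. The series names the assay as miCLIP and the sample titles as m6A-seq. Per the labels, mRNA was purified from total RNA, sonicated and immunoprecipitated with an antibody against m6A, and stranded libraries were made; no crosslinking step is described. The submitters' processing notes name FastQC 0.11.5, cutadapt 1.13 and Bowtie 1.1.2, and the human genome build hg19. The site names carry the name of the tool rbsSeeker and the change C to T. Its version, its filters and the way in which replicates were combined are not given in the sources used here. The labels assign the same list to the 3 replicates of a group, so lists are treated as pooled, with no SD and no n. Read totals per library were not used here.

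Each of the 3 deposited lists gives a site of 1 nt by chromosome, position and strand, with a site name that ends in a running number and a score. The score is a whole number set by the authors, at least 3 in every list, with a median of 14 in control, 11 with hairpin 1 and 15 with hairpin 2, a maximum of 19241, 1608 and 2586, and a sum over sites of 256360, 23420 and 51597. Its meaning is not stated in the deposited files. It was inferred here to be the number of reads over the site, because the running numbers order the sites exactly by a binomial probability. For a site with a score of n reads and m reads with the C-to-T change, this is the probability of m or more changed reads at a background rate that was fitted for each list. With rates of 1.57% for control, 1.43% for hairpin 1 and 1.00% for hairpin 2, whole numbers m exist that place all 3755, 482 and 697 sites in order. With shuffled scores, the highest number of sites in order over 3 shuffles was 712, 190 and 256. The order leaves a single possible m at 98.6%, 97.7% and 97.0% of sites. The remaining 51, 11 and 21 sites have bounds only and were left out of shares that need an exact m. On simulated lists of the same lengths with known rates, every single-valued m was recovered and every bound held the true value. The simulated sites were ordered by this same probability, so this checks the calculation and not what the score and the running numbers mean. C-to-T read numbers and shares are called reconstructed for this reason: they are an inference from the order of the names and the authors' score, and the file holds no such column. Reads without molecular identifiers are not independent molecules.

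Gene names, transcript regions, the DRACH motif and its pentamers, distances to stop codons and exon classes need an hg19 genome or annotation, which was not used here. The tests planned on them, on 13 gene lists and on genes by number of sites were therefore not run, and whether SETD2, METTL3, METTL14 or WTAP transcripts carry a site was not analysed here. No transcript level of SETD2 was analysed here either, so the knockdown itself is taken from the labels. Sites are reported by position, 1-based in hg19. Sites of chromosome Y are counted in totals and not named.

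Tests, alternatives and the rule for named sites were fixed before the data were examined. The rule for sites takes the 5 sites in all 3 lists and the 5 control sites in neither knockdown list with the highest score. Apart from the comparison of coverage and changed fraction at shared sites, the analyses of reconstructed read numbers, running numbers, chromosome shares and site groups were added after seeing the lists. For some tests of explanations among them, the predictions were written before those tests were run. Sites were shared when position and strand were equal. Shares have 95% exact Clopper-Pearson intervals. Shares of sites were compared with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the tests of the family (16 tests of read-number classes, 8 of coverage ranges, 48 of chromosomes). Medians were compared with two-sided permutation tests and paired values with two-sided sign-flip permutation tests of the mean, with 100000 resamples, or all sign patterns for 16 values or fewer. The overlap of the 2 knockdown lists is given beside the product of their lengths among control sites divided by the number of control sites, and as a Mantel-Haenszel odds ratio within coverage bins. Control sites were also thinned to knockdown depth in 1000 random draws, and groups of sites were compared with 1000 random control lists of knockdown length. For the thinning, the depth factor was taken from shared mitochondrial sites and a site was kept with at least 1 changed read among at least 3 reads. Alternatives changed the minimum score, the matching distance (10 or 50 nt), the merging of sites within 10 nt and the use of chromosome M. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used, and matplotlib 3.10.9 for the plots.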

Results

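The data are maps of N6-methyladenosine (m6A), the most common internal base modification of mRNA, at single-base resolution in HepG2, an established cell line from a human hepatocellular carcinoma. The series names the assay as miCLIP, in which an antibody against m6A is crosslinked to RNA fragments and reverse transcription over the crosslink leaves C-to-T changes beside the modified base. The sample titles say m6A-seq instead, and the protocol in the labels describes immunoprecipitation with an m6A antibody and no crosslinking step. Without crosslinking a C-to-T change need not mark m6A, so the sites are called m6A sites below only as the authors' lists name them. The cells stably carried a non-specific control shRNA (shCtrl) or either of 2 shRNAs against SETD2, called hairpin 1 (shSETD2_1) and hairpin 2 (shSETD2_2) here. SETD2 is the histone methyltransferase that trimethylates lysine 36 of histone H3 along transcribed genes. The labels give 3 replicates for each shRNA, 9 samples in all, and 1 pooled site list per shRNA, so no value below has a replicate error. Tests therefore compare pooled lists of sites and not the conditions, and they treat sites as independent, which neighbouring sites are not. Intervals are 95% exact Clopper-Pearson intervals and cover counting error only. Sites are given by chromosome, position and strand of build hg19, with start and end at the same base.

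Both SETD2 hairpins gave far shorter lists of m6A sites than the control shRNA. Nearly all sites of the control list were nuclear, so a much shorter list had to lose mainly nuclear sites. The control list held 3755 sites, the list of hairpin 1 held 482 and the list of hairpin 2 held 697, which is 7.79-fold and 5.39-fold fewer than control. Nuclear sites numbered 3730 in control, 458 with hairpin 1 and 671 with hairpin 2. Transcripts of the mitochondrial genome, which encodes subunits of the respiratory chain and the mitochondrial rRNAs, had similar numbers, with 25 sites in control, 24 with hairpin 1 and 26 with hairpin 2. These were only in part the same positions: 13 of the 25 control sites were found again with hairpin 1 and 12 with hairpin 2. Median coverage at these shared mitochondrial sites was 7.09-fold and 6.50-fold lower than in control. No replicate values stand behind the site numbers, and no test of the list lengths was made.

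The share of sites on the mitochondrial chromosome was higher in both knockdown lists. It was 0.666% of the control list (interval 0.431 to 0.981), 4.98% with hairpin 1 (3.22 to 7.32) and 3.73% with hairpin 2 (2.45 to 5.42). The odds ratios against control were 7.82 and 5.78, with adjusted p of 2.54e-09 and 8.92e-08 by two-sided Fisher's exact tests over 48 chromosome tests. Of the score summed over sites, mitochondrial sites held 19.8% in control, 27.7% with hairpin 1 and 16.6% with hairpin 2, so by reads only hairpin 1 was above control. All mitochondrial sites in the 3 lists were on the plus strand. Of the shares of the autosomes and chromosome X, 0 passed the adjusted threshold with either hairpin, the smallest adjusted p being 0.178 with hairpin 1 and 0.180 with hairpin 2 by Fisher's exact test. At an unadjusted p under 0.05, chromosome 11 had a lower share with hairpin 1 (2.07% against 4.53% in control) and chromosome 5 a higher share with hairpin 2 (5.74% against 3.68%). Mitochondrial sites were covered more deeply than nuclear ones, with a median score of 739 against 14 reads in control, 151 against 10 with hairpin 1 and 168.5 against 14 with hairpin 2.

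**Figure D1:**
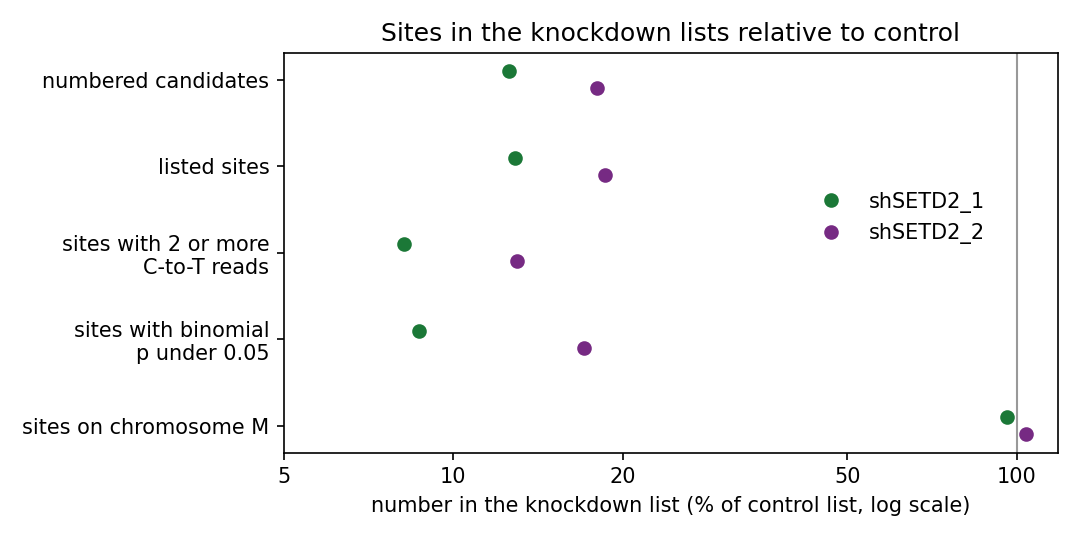
Each point gives a number in a knockdown list as a percent of the same number in the control list, on a log axis, for hairpin 1 (green) and hairpin 2 (purple); the numbered candidates are the highest running number in the site names of a list. Listed sites fell to 12.8% and 18.6% of control, while chromosome M held 24 and 26 sites against 25 in control.

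The running numbers in the site names fell with the number of sites. The highest number was 73157 in control, 9187 with hairpin 1 and 13154 with hairpin 2, which is 7.96-fold and 5.56-fold lower than control. Listed sites per 100 numbers came to 5.13 in control (interval 4.97 to 5.30), 5.25 with hairpin 1 (4.80 to 5.72) and 5.30 with hairpin 2 (4.92 to 5.70), and the control value lay within both knockdown intervals.

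Knockdown sites rested on fewer C-to-T reads than control sites. A single reconstructed C-to-T read lay under 40.9% of control sites (interval 39.3 to 42.5), 62.4% of the sites with hairpin 1 (58.0 to 66.8) and 58.7% with hairpin 2 (54.9 to 62.4). The odds ratios were 2.41 and 2.05, with adjusted p of 3.5e-18 and 1.91e-17 by Fisher's exact test. Sites with 2 or more C-to-T reads numbered 2218 in control, 181 with hairpin 1 and 288 with hairpin 2, a 12.3-fold and a 7.70-fold difference. Sites with 3 or more numbered 1508, 99 and 183. Sites with a binomial p under 0.05 at the list's fitted rate were 50.6% in control, 34.2% with hairpin 1 and 46.5% with hairpin 2. That difference passed with hairpin 1 (adjusted p = 2.96e-11, Fisher's exact test) and not with hairpin 2 (adjusted p = 0.0589, Fisher's exact test). For sites with a share under that rate, neither hairpin passed (adjusted p = 0.238 and 0.938, Fisher's exact test). The fitted rate was 1.57% in control, 1.43% with hairpin 1 and 1.00% with hairpin 2. A lower rate lets the same reads reach a binomial p under 0.05 more easily and makes a share under the rate rarer. Neither class therefore had the same limit in the 3 lists.

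The difference in reads per site was also seen within ranges of coverage. Among sites covered by 3 to 9 reads, 42.7% of control sites, 68.6% of hairpin 1 sites and 60.4% of hairpin 2 sites had a single C-to-T read, with adjusted p of 2.88e-12 and 1.65e-07 by Fisher's exact test. Among sites covered by 20 to 99 reads the shares were 43.3%, 64.0% and 67.5%, with adjusted p of 1.33e-05 and 1.25e-09 by Fisher's exact test. At 100 reads or more they were 17.2%, 24.1% and 30.8%, and the difference passed the threshold for hairpin 2 (adjusted p = 0.00198, Fisher's exact test) and not for hairpin 1 (adjusted p = 0.204, Fisher's exact test). The fitted background rate was lower in both knockdown lists, which could also give fewer changed reads at equal coverage. These tests do not separate the 2. Positions where nearly every read carried the change, a C-to-T share of at least 0.9, were compared without matching for coverage. They made up 11.5% of control sites, 5.60% with hairpin 1 and 8.03% with hairpin 2. The adjusted p was 7.88e-05 and 0.0107 by Fisher's exact test. Counting also the sites whose reconstruction leaves such a share possible, hairpin 2 came to 10.5% against 11.9% in control, which did not pass (adjusted p = 0.325, Fisher's exact test).

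**Figure D2:**
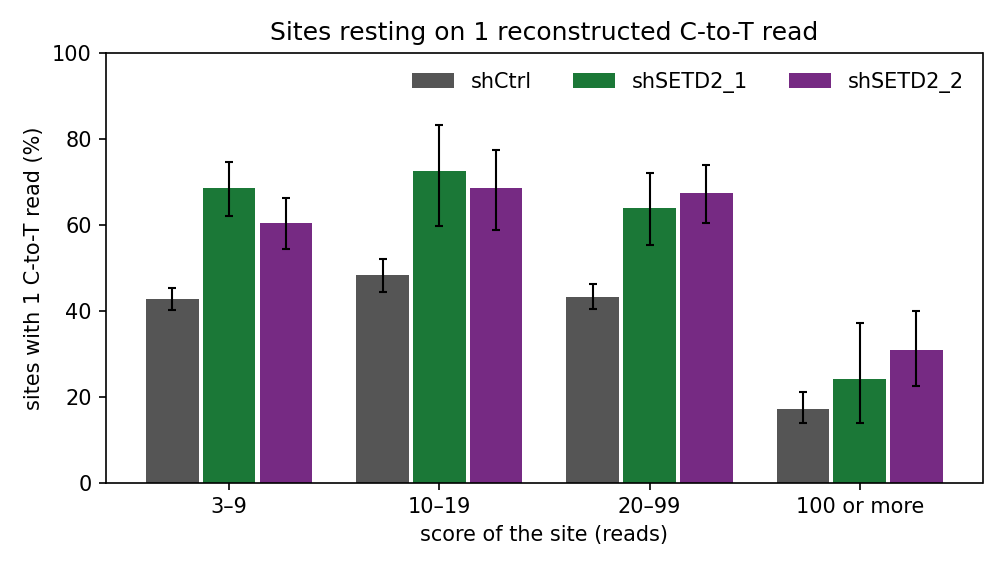
Bars give the percent of sites that rest on 1 reconstructed C-to-T read, by the score of the site in reads, for the control list (grey), hairpin 1 (green) and hairpin 2 (purple); error bars are 95% exact Clopper-Pearson intervals. At scores of 3 to 9 the bars stand at 42.7%, 68.6% and 60.4%.

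Few control sites were found again at the same base after SETD2 knockdown. Of the 3755 control sites, 225 were in the list of hairpin 1, or 5.99% (interval 5.25 to 6.80), and 244 were in the list of hairpin 2, or 6.50% (5.73 to 7.33). Without regard to coverage, mitochondrial sites recurred more often than nuclear ones. With hairpin 1, 13 of 25 mitochondrial control sites were found again against 212 of 3730 nuclear ones (52.0% against 5.68%, p = 2.5e-10, Fisher's exact test), and with hairpin 2, 12 of 25 against 232 of 3730 (48.0% against 6.22%, p = 1.06e-08, Fisher's exact test). Recurrence followed coverage, and mitochondrial control sites were covered more deeply. Among control sites predicted from their own reads to be found with a probability of 0.9 or more, 10 of 14 mitochondrial and 44 of 82 nuclear sites recurred with hairpin 1 (p = 0.256, Fisher's exact test), and 11 of 15 and 51 of 94 with hairpin 2 (p = 0.261, Fisher's exact test), so the difference did not pass at matched prediction. The knockdown lists also held many positions that the control list did not: 257 of 482 with hairpin 1, or 53.3% (48.8 to 57.8), and 453 of 697 with hairpin 2, or 65.0% (61.3 to 68.5).

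Control sites that recurred were more deeply covered at the median. Their median control score was 101 reads with hairpin 1 and 80.5 with hairpin 2, against 13 for the control sites not found again with either hairpin. Their median number of C-to-T reads was 5 against 2 for both hairpins. Two-sided permutation tests of the medians gave p = 1e-05, the smallest that 100000 resamples can give, for each of these differences. The median C-to-T share ran the other way, at 4.88% in recurring sites against 14.3% in the others with hairpin 1 (p = 2e-05, permutation test) and 5.77% against 14.3% with hairpin 2 (p = 1e-05, permutation test). Because a listed site has at least 1 changed read, shallow sites cannot have a low share, and this difference was not tested at matched coverage.

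At the shared sites the knockdown lists held several-fold fewer reads. Coverage at the 225 sites shared with hairpin 1 had a median 7.01-fold lower than in control and was lower at 208 of them. At the 244 sites shared with hairpin 2 it was 4.93-fold lower at the median and lower at 204. On the log2 scale the median ratio was -2.81 with hairpin 1 (quartiles -3.71 to -1.75) and -2.30 with hairpin 2 (quartiles -3.36 to -0.82), with p = 1e-05 for each, the smallest that the sign-flip permutation test can give. Mitochondrial sites fell alongside nuclear ones: coverage was 7.09-fold lower at 13 mitochondrial and 7.00-fold lower at 212 nuclear sites with hairpin 1, and 6.50-fold lower at 12 and 4.43-fold lower at 232 with hairpin 2. The nuclear minus mitochondrial difference was 0.02 on the log2 scale with hairpin 1 (p = 0.895, permutation test) and 0.55 with hairpin 2 (p = 0.35, permutation test). A shared site needs a score of at least 3 in the knockdown list, so shallow control sites that fell further are missing here. This bears more on nuclear sites, whose median score in the control list was 14 against 739 for mitochondrial ones. The nuclear fall may therefore be understated, and the nuclear and mitochondrial ratios are not directly comparable. Total reads per library were not used here, so these ratios are not scaled for sequencing depth.

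**Figure D3:**
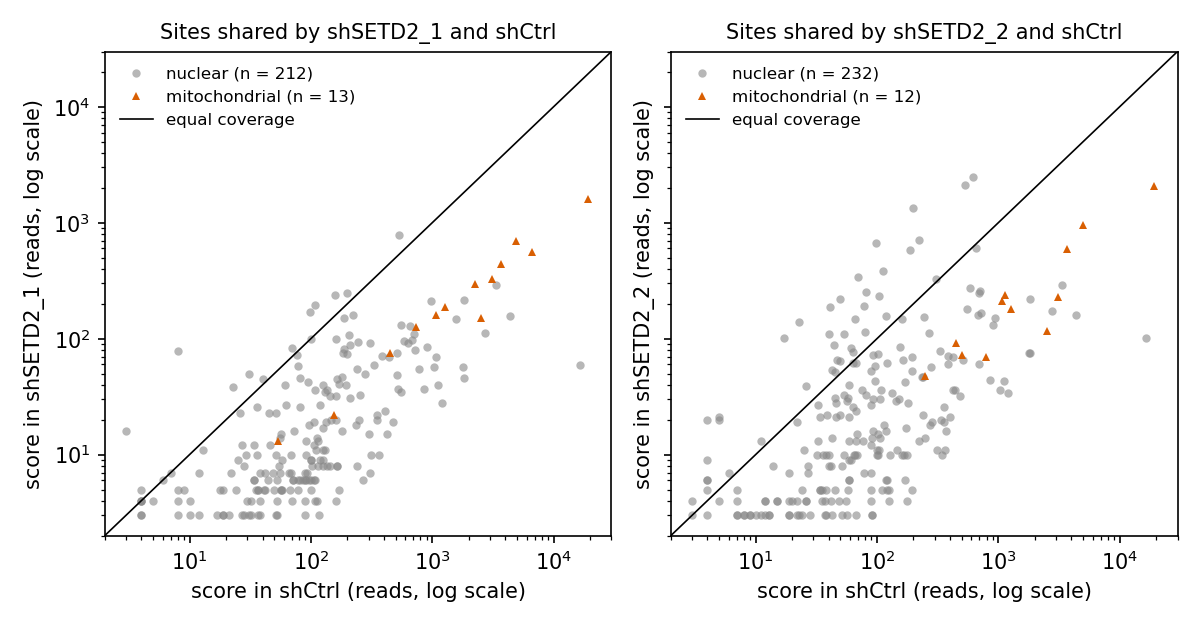
Each point is a site present at the same base in the control list (x axis, score in reads, log scale) and in a knockdown list (y axis, score in reads, log scale), for hairpin 1 on the left and hairpin 2 on the right; triangles are mitochondrial sites and the line marks equal coverage. Coverage was below the line at 208 of 225 sites with hairpin 1 and 204 of 244 with hairpin 2, and at all 13 and 12 mitochondrial sites.

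The fraction of reads with the C-to-T change at shared sites depended on their coverage. Over all shared sites with a resolved read number, the median share was 4.45% in control and 11.1% with hairpin 1 (198 sites, higher in the knockdown at 146), and 5.77% in control and 10.0% with hairpin 2 (217 sites, higher at 123). The paired difference had a median of 3.44 and a mean of 7.47 percentage points with hairpin 1 (50 sites lower). With hairpin 2 the median was 0.719 and the mean 5.14 points (83 sites lower). Sign-flip permutation tests of these means gave p = 1e-05 for both hairpins, the smallest they can give. A site needs at least 1 changed read to be listed, which sets a floor on the share where knockdown coverage is low. At shared sites with at least the median coverage in both lists, the mean difference with hairpin 1 was 1.1 percentage points (73 sites, 45 higher and 28 lower; p = 0.00571, sign-flip permutation test), against 7.47 over all sites. With hairpin 2 it was -0.104 against 5.14 (70 sites, 33 higher and 37 lower; p = 0.793, sign-flip permutation test). At shared sites with 50 or more reads in both lists, a limit chosen after seeing the data, the medians were 2.00% in control and 1.83% with hairpin 1 (44 sites, 23 higher and 21 lower; p = 0.81, sign-flip permutation test). With hairpin 2 they were 2.13% in control and 1.58% in the knockdown (57 sites, 19 higher and 38 lower, p = 0.00058, sign-flip permutation test). The median paired difference was -0.527 percentage points there, and the fitted background rate was 1.57% in control and 1.00% with hairpin 2. A lower background and less m6A at these sites cannot be told apart by this difference.

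The 2 hairpins retained overlapping sets of control sites. Of the control sites, 83 were found with both hairpins, against 14.6 for independent lists of the same lengths, an odds ratio of 12.2 (p = 1.82e-45, Fisher's exact test). Compared within 4 bins of control coverage, the number for independent lists was 32.1 and the odds ratio 5.43 (95% interval 3.89 to 7.58), and within 20 bins they were 40.9 and 4.39 (3.10 to 6.21), bins chosen after seeing the data. In control sites below the median score of 14 the overlap was 5 against 0.309 for independent lists, and at or above it 78 against 22.8. Both comparisons use the same control list, and sites with deep control coverage recurred more often with either hairpin. Outside the control list the hairpins shared 36 positions, while 221 were found with hairpin 1 alone, 417 with hairpin 2 alone and 3369 in control alone.

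The 5 best covered sites present in all 3 lists were 3 mitochondrial and 2 nuclear positions. The mitochondrial site at position 2241 of the plus strand had 19241 reads in control, 1608 with hairpin 1 and 2069 with hairpin 2, with a C-to-T share between 3.02% and 3.35% in control, between 3.61% and 3.79% with hairpin 1 and between 4.01% and 5.36% with hairpin 2. The mitochondrial site at 11284 (plus strand) had 4950, 698 and 963 reads with shares of 2.67%, 2.87% and 2.39%. The mitochondrial site at 4919 (plus strand) had 3686, 438 and 597 reads, with knockdown shares of 2.74% and 3.02% and a control share between 4.21% and 4.26%. Coverage at the chromosome 1 site at 16826300 (plus strand) fell further than at the others, from 16513 reads in control to 59 and 102, which is 280-fold and 162-fold lower. The share at this site is not resolved, with lower bounds of 3.43% in control, 33.9% with hairpin 1 and 27.5% with hairpin 2 and upper bounds of 100%. The chromosome 1 site at 91853097 (minus strand) went from 4399 to 157 and 160 reads, 28.0-fold and 27.5-fold lower. Its share was between 5.18% and 6.48% in control, 3.82% with hairpin 1 and 2.5% with hairpin 2.

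The 5 best covered control sites absent from both knockdown lists had C-to-T shares between 1.55% and 3.69%, where the median of all control sites with 20 or more reads and a resolved read number was 3.67%. That median includes far shallower sites, where a single changed read already gives a higher share, and the comparison was not matched for coverage. The chromosome 18 site at 12326396 (plus strand) had 102 changed reads among 6489, a share of 1.57%, and the chromosome 12 site at 46754879 (minus strand) had 54 among 3479, or 1.55%. The background rate fitted to the control list was also 1.57%. The others were the chromosome 4 site at 7032275 (plus strand; 23 of 1293 reads, 1.78%), the chromosome 8 site at 27455529 (minus strand; 30 of 814, 3.69%) and the mitochondrial site at 9605 (plus strand; 17 of 741, 2.29%).

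How often sites lay in groups depended on the length of the control list compared. With groups formed from same-strand sites at gaps of up to 1000 nt, 18.4% of control sites had such a neighbour (interval 17.2 to 19.7), against 12.0% with hairpin 1 (9.27 to 15.3) and 9.18% with hairpin 2 (7.14 to 11.6). The odds ratios were 0.607 (p = 0.000376, Fisher's exact test) and 0.448 (p = 2.94e-10, Fisher's exact test). Shorter lists leave fewer neighbours by construction, and the direction turned against control lists of equal length, a comparison chosen after seeing the data. Random control lists of 482 sites had 3.14% of sites in groups (95% of 1000 draws between 1.24% and 5.39%) and those of 697 sites 4.45% (2.44% to 6.60%), both below the knockdown values (p = 0.002, the smallest these permutation draws can give). With chromosome M left out, the shares were 7.64% with hairpin 1 against 2.78% in random lists (p = 0.002, permutation draws) and 5.66% with hairpin 2 against 4.07%, which did not pass (p = 0.158, permutation draws). The best covered control sites, taken in equal number, had 21.2% and 20.1% in groups, above the knockdown values (p = 0.000184 and p = 9.5e-09, Fisher's exact test). Of the 294 nuclear regions with 2 or more control sites in a group formed over the 3 lists, 202 held no site with either hairpin, and of the 17 with 4 or more control sites, 5 held none. The 4 nuclear regions with the most control sites, 5 each, are named here and were chosen after their values were seen. Chromosome 2 from 21232178 to 21234077 (minus strand) held 5 control sites and 2 sites with each hairpin. The adjoining stretch from 21230064 to 21231059 held 5 control sites, 2 with hairpin 1 and 0 with hairpin 2. Chromosome 2 from 20647453 to 20647968 (plus strand) held 5, 2 and 3 sites, and chromosome 1 from 564545 to 568523 (plus strand) held 5, 5 and 4. Nuclear here means placed on a chromosome other than M. Whether reads of mitochondrial origin were placed on similar nuclear sequence, as could happen in such a region, was not tested. Among regions with 4 control sites, also chosen after their values were seen, chromosome 17 from 80320985 to 80321484 (plus strand) held 0 with either hairpin, and chromosome 19 from 1555770 to 1556340 (minus strand) held 0 with hairpin 1 and 1 with hairpin 2. Others with 4 control sites kept more. Chromosome 7 from 94294669 to 94295439 (plus strand) held 3 and 2 sites, and chromosome 14 from 38060488 to 38061342 (minus strand) held 1 and 4.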

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

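The 2 hairpins differed from each other against the same control list, a comparison of lists chosen after seeing the data. At the 75 nuclear sites found in all 3 lists, coverage with hairpin 2 exceeded that with hairpin 1 by a median of 0.70 on the log2 scale, or 1.62-fold, and was higher at 61 of the 75 sites (p = 1e-05, the smallest the sign-flip permutation test can give). At the 8 mitochondrial sites in all 3 lists it was 1.24-fold higher at the median and higher at 5 of 8 (p = 0.406, exact sign-flip permutation test). The nuclear and mitochondrial medians differed by 0.39 on the log2 scale (p = 0.373, permutation test). Sites are not replicates, and the 2 lists were not scaled for depth.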

How the results depend on the processing

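No paired analysis was possible because each shRNA has a single pooled list, and for the same reason leaving out replicates could not be run. Alternatives on DRACH or RRACH motifs, regions, stop codon distances, exon classes, pentamers, gene lists and genes with sites, with the shortened control lists meant for motif and region shares, were not run, since no hg19 genome or annotation was used here. Of the 27 alternative settings fixed beforehand that were run, 26 kept direction and threshold side or stayed within the interval of the value, among them a minimum score of 14, merging within 10 nt, leaving out chromosome M for site numbers, and matching within 10 or 50 nt. The other is the mean difference in C-to-T share at shared sites with hairpin 2, 5.14 percentage points higher than control over all sites and -0.104 at sites with at least the median coverage in both lists (p = 0.793, permutation test). With hairpin 1 that setting left 1.1 of 7.47 points, still past the threshold (p = 0.00571, permutation test). Of the 48 settings chosen after seeing the data, 30 stayed and 18 did not. At 50 or more reads in both lists that difference was -0.0520 with hairpin 1 and -0.985 with hairpin 2. With 2 or more C-to-T reads the knockdown lists came to 8.16% and 13.0% of the control list, and with a binomial p under 0.05 to 8.69% and 17.1%, against 12.8% and 18.6% as deposited. Per numbered candidate they came to 102% and 103%. Control sites found again came to 4.10% and 4.91% with 2 or more C-to-T reads and to 3.58% and 5.27% with a binomial p under 0.05. Against random control lists of equal length, the odds ratios of sites in groups turned from 0.607 and 0.448 to 4.22 and 2.17, and to 2.89 and 1.41 without chromosome M, because shorter lists hold fewer neighbours. Knockdown sites absent from control came to 58.8% and 69.1% with a binomial p under 0.05. In all settings with a binomial p, it was taken at each list's own fitted rate, so that filter was not equally strict in the 3 lists. The cause of the other shifts was not tested. Depth limits the shares: at a score of 3 the smallest listed C-to-T share is 33.3%.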

Other observations

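Some shared sites went against the general fall in coverage, 12 of 225 with hairpin 1 and 39 of 244 with hairpin 2. Of the 83 sites in all 3 lists, 8 had a higher score in both knockdown lists than in control, a group chosen after its values were seen. The chromosome 12 site at 56538455 (plus strand) had 529 reads in control, 792 with hairpin 1 and 2112 with hairpin 2, with C-to-T shares of 2.65%, 1.26% and 1.18%. The chromosome 12 site at 45826129 (plus strand) had 198, 250 and 1341 reads, and the chromosome 10 site at 120927234 (minus strand) had 98, 171 and 675. A further 36 positions were found with both hairpins and not in control. Their control coverage is not known, since the lists give coverage at listed sites only. Among them, the chromosome 8 site at 26268505 (plus strand) had 507 and 2586 reads, with C-to-T shares of 1.38% and 0.851%. The chromosome 19 site at 10244025 (minus strand) had 654 and 1877 reads, with shares of 2.45% and 1.39%. These sites were also chosen after their values were seen. Of the 36, 18 had 2 or more C-to-T reads in both lists and 4 were mitochondrial. The fitted background rates were 1.57% in control, 1.43% with hairpin 1 and 1.00% with hairpin 2. At 26268505 both shares lay below the rates of their lists, and at 10244025 both lay above. High coverage at the sites named here does not by itself mark m6A.

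Of the tests that follow, the count of numbered candidates and the overlap within coverage bins were chosen after their results were seen, and the predictions of the others were written before they were run. For the shorter knockdown lists, fewer reads in the knockdown libraries is a candidate explanation that the tests leave open: listed sites per numbered candidate were at least 1.02 times the control value with either hairpin, but what the numbers count is inferred, so this does not point to read number. Thinning the control reads 7.09-fold and 6.50-fold kept 3.09 and 3.10 times the sites actually found again, above the bound of 1.5 set beforehand as evidence against depth alone. That bound is not taken here to exclude depth, because the same thinning kept 1.45 and 1.61 times the mitochondrial sites found again, although these set the depth factor, and thinning reuses the reads by which control sites were chosen. Loss of m6A from nuclear transcripts after SETD2 knockdown stays open too: among control sites that thinning predicts at a probability of 0.9 or more, 44 of 82 nuclear and 10 of 14 mitochondrial sites were found with hairpin 1, and 51 of 94 and 11 of 15 with hairpin 2 (largest p = 0.261, Fisher's exact test). With so few mitochondrial sites, depth and loss of methylation cannot be told apart here.

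For the sites present in all 3 lists, high coverage in every list stays open as an explanation. Their median control score was 179 reads against 14 for other control sites, and the odds ratio of the overlap between hairpins went from 12.2 to 5.43 within 4 bins of control coverage and to 4.39 within 20 bins (95% interval 3.10 to 6.21). Control coverage at this resolution leaves part of the overlap, but coverage in the knockdown libraries was not matched, since the lists give it at listed sites only. Positions where the HepG2 genome differs from the reference were looked for only by a C-to-T share of 0.9 or more in every list. Between 1 and 8 of the 83, at most 9.64%, have such a share. The bounds of the reconstruction leave it open whether the 5% set beforehand is reached. Differences carried by only part of the genome copies would give lower shares and are missed, so these counts do not limit this explanation. In control, such a share was possible at 12.0% of these sites and at 11.9% of the other control sites (odds ratio 1.02, p = 0.865, Fisher's exact test). That comparison was not matched for coverage, and shallow sites reach such a share with few changed reads, so it does not bear on genome differences.

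For the sites with a single C-to-T read, background mismatches rather than m6A are a candidate explanation. Knockdown sites with a single changed read were found in control less often than knockdown sites with 2 or more in 8 of 8 coverage ranges over both hairpins, in 4 of them with an adjusted p under 0.05 by Fisher's exact test. At 100 reads or more, 2 of 14 single-read sites with hairpin 1 were in the control list against 25 of 44 others, and 6 of 36 against 40 of 81 with hairpin 2. The range of 3 to 9 reads held the most single-read sites, and neither hairpin passed there. With hairpin 1, 42.6% of 155 single-read sites were in control against 45.1% of 71 others (adjusted p = 0.773, Fisher's exact test). With hairpin 2 it was 26.2% of 168 against 33.6% of 110 (adjusted p = 0.256, Fisher's exact test). Sites with little m6A would recur less often too, and the test does not separate these from mismatches.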
